A study of Mus musculus with 4 samples.

How the data were processed

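Single-cell RNA sequencing was run on epithelial cells sorted from mouse distal colon, per the labels. The series holds 4 libraries from droplet capture with the 10x Genomics kit, 1 per group. The nociceptor knockout library came from mice carrying the Nav1.8 Cre driver together with a diphtheria toxin A allele, and its control from mice without the Cre driver. The Ramp1 knockout library came from mice carrying the Villin Cre driver and floxed Ramp1 alleles, and its control from mice with floxed alleles and no Cre driver. Per the labels, controls were littermates, each library aimed at 10000 cells and viability was above 88%. The number of mice behind each library is not given in the sources used here, nor is the part of Ramp1 that the floxed alleles remove.

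The deposited matrices hold UMI counts per gene and droplet barcode, whole numbers without normalization. Cell Ranger 4 wrote them, per the file headers, and the genome build is mm10, per the submitters' processing notes. They are unfiltered: each file lists between 2422389 and 2932072 barcodes and 32285 genes. Gene symbols were taken from the files. Of the gene identifiers, 32158 match GENCODE mouse release 21, whose GRCm38 coordinates are the ones printed.

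A barcode was kept with at least 1000 UMIs, at least 500 genes and at most 20% of UMIs from mitochondrial genes. The mitochondrial limit removed 27.9% of the barcodes that passed the other limits in the nociceptor control, 26.8% in the nociceptor knockout, 30.0% in the Ramp1 control and 28.0% in the Ramp1 knockout. Scrublet, run through scanpy 1.11.5, scored doublets per library, and the top-scoring share was removed at 0.8% per 1000 cells, which took out 758, 847, 546 and 530 barcodes in the same order. After these steps 33749 cells remained.

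Cells of the 4 libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used, and a graph of 15 shared nearest neighbours was partitioned by the Leiden method at resolution 1 (python-igraph 0.11.9, scikit-learn 1.9.0). Clusters were named from marker lists for 13 cell types fixed beforehand, with at least 3 detected markers required. A cluster of low-UMI barcodes was left unnamed by a limit set after the data had been seen. Values were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and anndata 0.12.19, and plots were drawn with matplotlib 3.10.9.

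UMI counts were summed per library and cell class and divided by the total of that class to give CPM. List medians, correlations and the gene ratios under the alternatives were taken from log2 ratios with 1 UMI added to each sum. With 1 library per group no test between conditions was possible, so the differences have no replicate check and carry no p-values. Each knockout was set against its own control. The control libraries were also set against each other as the only view of spread between libraries without a knockout, though they differ in mouse line and in sex genes. Sums carry exact Poisson intervals, ratios of sums exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95% and covering counting error only. A fold against a count of 0 was computed against a floor of 3 counts over the group. The intervals and list percentiles were tested on simulated data drawn from the real libraries' means and sizes. For the nociceptor comparison over all epithelial cells (13581 genes), 95.4% of intervals held the true ratio and 90% of genes set to a fold of 1.5 had an interval excluding 1, against 100% at folds of 2 and 4. For the Ramp1 comparison (13484 genes), the values were 95.3%, 98.8%, 100% and 100%. Of 100 unchanged lists, 5 in the nociceptor and 6 in the Ramp1 comparison fell outside the central 95% of random lists. These simulated counts held counting noise only, without spread between libraries or genes that change together. They show how intervals and percentiles behave under counting error, not between real libraries.

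Gene lists were fixed before the data were examined, 21 in all. A list member was measured with at least 20 UMIs over the compared libraries and counted as higher or lower at a fold of 1.5. The median log2 ratio of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Its percentile describes these libraries only. Between the controls lists also reached the ends: in goblet-like cells the interferon list stood at percentile 100 and colonocyte transport at 0. A percentile of 0 or 100 is therefore no mark of a knockout by itself.

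Genes were named by a rule fixed beforehand. A gene needed at least 100 UMIs over the compared libraries and a knockout CPM outside the range of both controls. Genes were ranked by the interval bound nearest to 0. The top 10 per direction were taken in goblet-like cells and the top 5 per direction in colonocyte-like cells and in all epithelial cells. Mitochondrial, ribosomal, haemoglobin, immunoglobulin and unnamed genes were left out of the ranking, as were Xist, Tsix and the Y-linked Ddx3y, Kdm5d, Uty and Eif2s3y. Other X-linked genes stayed in. Every measured member of the goblet secretory product and CGRP receptor family lists was also named, as were the 2 members of any other described list farthest from 0. A few genes that met these rules are not reported here.

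Free RNA was read from barcodes with 200 to 700 UMIs, which form the peak of empty droplets, at their mean content per droplet. The profile planned beforehand, from barcodes with 10 to 100 UMIs, lies below that peak and was kept as an alternative. To compare shares of cells with a UMI, cells were thinned to 5000 UMIs and shallower cells left out.

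The alternatives fixed beforehand were a minimum of 500 or 2000 UMIs, a limit of 0.1 of the 99th percentile of the top 10000 barcodes, a mitochondrial limit of 10% or 40%, no doublet removal, resolutions of 0.5 and 2, genes scaled within each library, subtraction of the 10 to 100 UMI profile at 10% of each sum, cells thinned to 1000 UMIs, other count minimums, and log2 ratios centred on their median. These were fixed for the goblet-like share, Ramp1, goblet product, correlation and named gene results, and running them on Ang4 and 5 other gene lists was decided after seeing the data. Alternatives chosen after seeing the data were subtraction of the 200 to 700 UMI profile, counting the low-UMI cluster as goblet-like, and clustering without 68 genes of 6 lists that define goblet-like or interferon-rich clusters.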

Results

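The data are single-cell transcriptomes of sorted epithelial cells from the mouse distal colon, in 4 libraries with 1 library per group. One pair sets mice whose Nav1.8-expressing sensory neurons (nociceptors) carry diphtheria toxin A against littermates without the Cre driver. The other pair sets mice with Ramp1 deleted in Villin-expressing epithelium against littermates that keep Ramp1. Filtering left 209631029 UMIs for the nociceptor control, 236402242 for the nociceptor knockout, 192168783 for the Ramp1 control and 165760999 for the Ramp1 knockout, in 8979, 9440, 7717 and 7613 cells with medians of 22759, 24875.5, 24401 and 21691 UMIs. Median mitochondrial shares lay between 8.24% and 8.49%. No group has a replicate library, so values are given without tests, and 95% intervals in brackets cover counting error only.

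Clustering gave 22 clusters of cells. Goblet-like cells fell in cluster 5, led by Mptx1, Sval1, Reg4, Ang4 and Clca1, in cluster 9, led by Plet1, Spdef, Mt3 and Muc2, and in the smaller cluster 18, led by Spink1, Zg16 and Tff3. Cluster 5 held 55.3% of the goblet-like cells in the nociceptor control, 62.1% in the nociceptor knockout, 51.8% in the Ramp1 control and 40.2% in the Ramp1 knockout, and cluster 9 held 32.7%, 30.3%, 38.6% and 48.7%. The goblet-like class is therefore weighted to cluster 9 in the Ramp1 knockout and to cluster 5 in the other 3 libraries. Ramp1 is itself among the 10 leading genes of cluster 5 and was not left out of the main clustering. These cluster shares therefore cannot be read as independent of its deletion. Colonocyte-like cells spread over 8 clusters, of which cluster 8 was led by the interferon-induced genes Ifit2, Ifit1bl1 and Gbp2. Stem-like, cycling, tuft-like and enteroendocrine-like clusters were also named, and 5 clusters stayed unnamed. Of these, cluster 13 was led by Mcm3, Mcm6 and Hells, and Mcm6 is a marker of the cycling class. Clusters 3, 7 and 11, led by Aqp4, Sult1a1 and Fxyd4, had under 3 markers detected. The cycling and colonocyte-like shares therefore need not hold all such cells. A cluster of barcodes with a median of 1102 UMIs, led by Gm42418, AY036118 and Lars2, held 1.97%, 4.41%, 0.402% and 0.342% of cells in the library order above. Its next genes included Ang4, Retnlb and Tff3, and goblet was the best-matching cell type, with 3 markers detected. It was kept out of the goblet-like class by a limit set after the data were seen. Markers of lymphoid, myeloid, B or plasma, fibroblast, endothelial, neural and erythroid cells summed to at most 2.03 CPM per cell type in any library.

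Ramp1 (ENSMUSG00000034353, GRCm38 chromosome 1, 91179822 to 91225196) encodes the subunit that pairs with the receptor encoded by Calcrl to bind the nociceptor peptide CGRP. It was the targeted gene of the epithelial knockout. Over all epithelial cells it stood at 130 CPM (128 to 131) in the nociceptor control, 126 CPM (124 to 127) in the nociceptor knockout and 133 CPM (131 to 135) in the Ramp1 control. In the Ramp1 knockout it stood at 14.9 CPM (14.3 to 15.5), which is 0.112 of its control (0.108 to 0.117) and goes with the label. The labels do not say which part of the gene is deleted, so 3′ tags outside that part would still be counted. Scn10a, the gene of Nav1.8, had 0 UMIs in the epithelial cells of every library, with upper 95% bounds between 0.0156 and 0.0223 CPM, so these data cannot check the nociceptor label.

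Where in the colon epithelium Ramp1 is expressed can be read within each library. Goblet-like cells held 879 CPM of Ramp1 (868 to 890) in the nociceptor control and 998 CPM (985 to 1011) in the Ramp1 control, against 15.02 CPM (14.5 to 15.6) and 10.9 CPM (10.4 to 11.4) in all other epithelial cells. The ratio was 58.5 (56.2 to 60.9) and 91.9 (87.7 to 96.5). Cycling cells held 113 and 54.6 CPM, enteroendocrine-like cells 103 and 125 CPM, and tuft-like cells 57.6 and 55.7 CPM. Within the cycling class Ramp1 lay mostly in cluster 19, at 474 and 499 CPM, where Muc2 stood at 7868 and 7544 CPM. Cycling cluster 12 held 3.46 and 2.70 CPM of Ramp1 and cycling cluster 14 held 2.32 and 1.62 CPM. Colonocyte-like cells, at 3.35 and 2.60 CPM, lay near the 2.09 and 1.66 CPM that free RNA brings. At 5000 UMIs per cell, 90.1% (88.1 to 91.8) and 90.7% (88.7 to 92.5) of goblet-like cells carried a Ramp1 UMI, against 1.85% and 1.44% of colonocyte-like cells, the class nearest to background. Without thinning the shares were 97.8% and 95.2% of goblet-like cells, at medians of 24109.5 and 23830.5 UMIs, and 6.93% and 5.76% of colonocyte-like cells, at 22012 and 24076.5 UMIs. Over the alternatives tried the ratio of goblet-like to other cells lay between 43.8 and 1144 in the nociceptor control and between 66.2 and 6796 in the Ramp1 control, highest with the free RNA profile of 10 to 100 UMIs subtracted.

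Calcrl, the partner of Ramp1, was scarce. Goblet-like cells held 2.87 CPM (2.28 to 3.58) in the nociceptor control and 2.52 CPM (1.93 to 3.25) in the Ramp1 control, stem-like cells 3.39 and 2.55 CPM and enteroendocrine-like cells 6.35 and 9.02 CPM. In colonocyte-like cells Calcrl stood at 0.00905 and 0.0611 CPM, from 1 and 5 UMIs (0.000229 to 0.0504 and 0.0198 to 0.143). Of the other genes on the list named CGRP receptor family, not all of which encode receptors, Crcp and Adm were measured in goblet-like cells. They stood at 17.3 and 3.31 CPM in the nociceptor control.

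**Figure D1:**
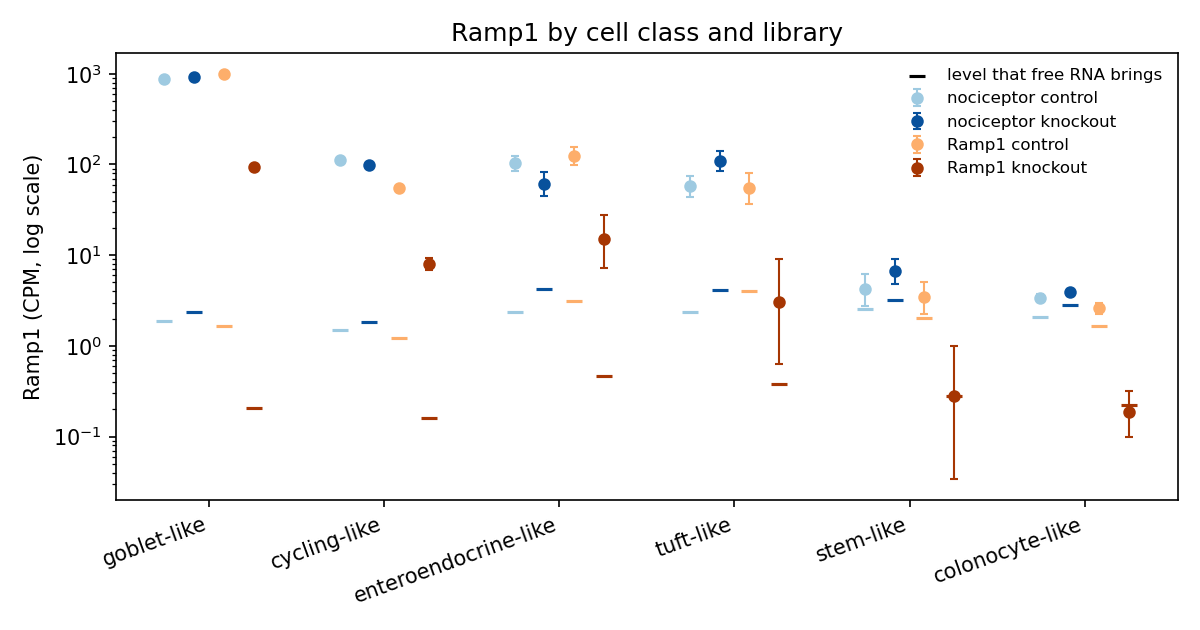
Ramp1 CPM on a log axis per cell class in the 4 libraries, with 95% Poisson intervals as bars and the level that free RNA brings as short dashes. In goblet-like cells the Ramp1 knockout stands at 94.7 CPM against 998 CPM in its control, while colonocyte-like cells of every library stand near the free RNA level.

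The nociceptor comparison asks how the colon epithelium differs when nociceptors are ablated. Interferon-induced genes were higher in the nociceptor knockout in goblet-like, colonocyte-like, cycling and stem-like cells, and in all epithelial cells by a median log2 ratio of 1.86. Genes of MHC class II antigen presentation and heat shock chaperones were also higher, with medians of 1.15 and 0.99. Goblet-like cells carried more of the secreted products Ang4, Retnlb and Itln1 and less mRNA of absorptive transport and bile acid genes. Ramp1 itself was close between the libraries in goblet-like cells, at 879 and 926 CPM, and Calcrl stood at 2.87 and 3.71 CPM. Log2 ratios here and below are knockout over control.

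Goblet-like cells were 12.3% (11.6 to 13.0) of the nociceptor control and 10.9% (10.3 to 11.6) of the nociceptor knockout, a ratio of 0.888 (0.820 to 0.962). The direction turned in 2 alternatives: the ratio was 1.06 with cells thinned to 1000 UMIs and 1.07 with the low-UMI cluster counted as goblet-like. Cycling cells were 6.04% and 4.63% (ratio 0.767, 0.678 to 0.867), stem-like cells 3.59% and 3.01% (0.839, 0.717 to 0.981) and tuft-like cells 0.568% and 0.403% (0.709, 0.466 to 1.08). Enteroendocrine-like cells were 0.613% and 0.456% (0.744, 0.500 to 1.11) and colonocyte-like cells 55.0% and 57.7% (1.05, 1.02 to 1.08). Cells of unnamed clusters were 22.0% and 22.8% (1.04, 0.986 to 1.10). Between the control libraries the ratio of Ramp1 control to nociceptor control was 1.05 for goblet-like, 1.60 for cycling, 1.41 for stem-like and 0.815 for colonocyte-like cells. It was 1.19 (0.807 to 1.74) for tuft-like and 1.12 (0.770 to 1.63) for enteroendocrine-like cells. The cycling, stem-like and colonocyte-like ratios of the nociceptor pair thus lie nearer to 1 than those of the controls, and the goblet-like, tuft-like and enteroendocrine-like ratios lie farther from 1. The tuft-like and enteroendocrine-like ratios rest on 38 to 55 cells per library and their intervals hold 1, so their order is within counting error.

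Among goblet secretory products, 15 genes were measured in goblet-like cells, with 3 higher, 0 lower and a median log2 ratio of 0.20 (percentile 100 of matched random lists). Within cluster 5 the median was 0.11 with 0 higher, within cluster 9 0.18 with 3 higher and within cluster 18 0.43 with 7 higher and 3 lower. With cells thinned to 1000 UMIs and clustered again it was 0.0028. Outside goblet-like cells the list stood at 0.18 in colonocyte-like cells (2 of 15 higher), 0.01 in cycling cells (2 of 15 lower) and 0.75 in stem-like cells (8 of 14 higher), with free RNA left in. The Muc2-rich cluster 19 was 19.7% of the cycling class in the control and 16.9% in the knockout. Ang4 (ENSMUSG00000060615, chromosome 14, 51763878 to 51773590), an antimicrobial ribonuclease, stood at 4002 CPM in the control and 6144 CPM in the knockout, a log2 ratio of 0.62 (0.61 to 0.63). Retnlb, a resistin-like molecule secreted to the lumen, stood at 5474 and 8352 CPM (0.61, 0.60 to 0.62). The lectin Itln1 stood at 114 and 182 CPM (0.68, 0.61 to 0.74). Clca1, a mucus-processing protease, stood at 7837 and 11730 CPM (0.58), Fcgbp at 3761 and 5374 CPM (0.51), Spink4 at 0.33, and Muc2, the main gel-forming mucin, at 15450.1 and 17788 CPM (0.20). Tff3 (0.20), Sval1 (0.12), Muc13 (0.08), Klk1 (0.05), Zg16 (0.02), Reg4 (0.01), Pigr (-0.00) and Agr2 (-0.04) completed the list. The control libraries differed more in several of these genes than either knockout from its control: the nociceptor control held 8.61 times the Ang4, 12.4 times the Retnlb and 5.73 times the Itln1 of the Ramp1 control in goblet-like cells. Over the list the Ramp1 control stood at a median of -0.09 against the nociceptor control, with 5 of 15 lower, at percentile 0.185.

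In the interferon response list, 12 of 15 measured genes were higher in goblet-like cells (median 1.02, with 1.09, 1.14 and 0.13 within clusters 5, 9 and 18), 14 of 15 in colonocyte-like cells (1.79) and 14 of 15 in all epithelial cells, each at percentile 100. Cycling cells (15 of 15, median 1.29) and stem-like cells (11 of 11, median 1.41) had the same direction. Ifi44 (chromosome 3, 151730922 to 151749960) stood at 6.86 and 38.6 CPM in all epithelial cells (2.49, 2.41 to 2.57) and Ifit2 at 6.58 and 36.8 CPM (2.48). The ubiquitin-like modifier Isg15 stood at 186 and 796 CPM. The interferon-led cluster 8 held 133 cells of the control and 1113 of the knockout. Between the controls the list median was 0.60 in all epithelial cells, with 8 of 15 genes higher in the Ramp1 control. MHC class II genes, which present peptides to CD4 T cells, were higher in 7 of 7 measured in all epithelial cells: H2-Aa stood at 6.08 and 19.2 CPM and H2-Ab1 at 18.6 and 44.2 CPM. In goblet-like cells the MHC median was 0.36, with 0 of 6 higher. The controls differed by 1.89 in this list in goblet-like cells and by 2.24 in colonocyte-like cells, the Ramp1 control being higher.

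Heat shock chaperones were higher in 8 of 11 genes in goblet-like cells (median 1.16), 9 of 11 in colonocyte-like cells (1.06) and 8 of 11 in all epithelial cells. Hsph1 (chromosome 5, 149614287 to 149636376) stood at 28.3 and 157 CPM in goblet-like cells (2.47, 2.36 to 2.59) and Hspb1 at 4.42 and 15.7 CPM (1.83, 1.54 to 2.13). Between the controls the median was -0.23 in goblet-like cells and -0.01 in all epithelial cells. The ER folding list had a median of 0.29 in goblet-like cells with 1 of 22 genes higher: Creld2 stood at 111 and 168 CPM and the chaperone Hspa5 at 1364 and 1988 CPM.

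Absorptive transcripts counted in goblet-like cells were lower in the knockout. Of 16 colonocyte transport genes, 9 were lower and 0 higher (median -0.65, percentile 0): the water channel Aqp8 stood at 90.3 and 34.2 CPM (-1.40, -1.51 to -1.29) and the carbonic anhydrase Car1 at 1454 and 588 CPM (-1.31). In colonocyte-like cells the same list was level, with 14 genes measured, 0 lower and a median of -0.05. The colonocyte-like class is mixed differently in this pair: cluster 4, which Ly6m and Aqp8 lead, was 27.0% of the class in the control and 13.3% in the knockout, and the interferon-led cluster 8 was 2.70% and 20.4%. Bile acid and xenobiotic genes had 9 of 14 lower in goblet-like cells (-0.66), with Slc51a at 10.7 and 2.69 CPM and Cyp2c55 at 348 and 129 CPM. The transport median lay between -1.41 and -0.21 over the alternatives. Between the controls the transport list stood at -0.32 in goblet-like cells (7 of 16 lower and 1 higher in the Ramp1 control, percentile 0). Cholesterol synthesis genes had 6 of 16 lower (-0.51), with Lss at 18.2 and 10.4 CPM and Hmgcs1, an early enzyme of the pathway, at 207 and 124 CPM. Within cluster 5 this median was -0.67 with 10 lower, and within cluster 9 it was -0.10 with 0 lower. The antimicrobial list had 3 higher and 3 lower of 13 (-0.22), with the lectins Reg3b at 144 and 19.4 CPM and Reg3g at 33.7 and 9.18 CPM. Its median had the other sign in colonocyte-like cells (0.40) and in all epithelial cells (0.43). Of the Reg3b UMIs in control goblet-like cells, 10 of 1104 cells carried the larger part.

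The other lists had medians between -0.31 and 0.06 in goblet-like cells. Goblet fate (0.06) included Notch1 at -0.82 and Foxa2 at 0.32, mucin O-glycosylation (0.06) Chst4 at 0.34 and Galnt3 at 0.22, and granule exocytosis (0.06) had 1 of 16 higher and 1 lower. Immediate early and cAMP response genes (0.02) had 0 of 19 beyond a fold of 1.5, with Nr4a2 at 0.51 and Sik1 at 0.44. Cell cycle (-0.31) included Cenpa at -0.81 and Aurka at 0.81, cytokines and chemokines (-0.19) Cxcl1 at 1.77 and Il18 at -0.62, stem and Wnt genes (-0.13) Lgr5 at -1.27 and Ascl2 at -0.86, and junction genes (-0.13) Cldn8 at -0.64 and Cldn2 at -0.33. Hox and regional genes (-0.06) included Hoxb8 at -0.43 and Cdx2 at -0.36. The CGRP receptor list had a median of -0.01 over 4 measured genes, with Ramp1 at 0.07, Calcrl at 0.37 (-0.06 to 0.80), Crcp at -0.16 and Adm at -0.09. Of the nociceptor list, Tac1 alone was measured in goblet-like cells, at 2.30 and 2.38 CPM. The sex gene list had a median of -0.14 over 4 measured genes, with Kdm5d at -0.22 and Ddx3y at 0.17.

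Ranked by the interval bound nearest to 0, the genes highest in knockout goblet-like cells were AA465934 (0.898 and 12.7 CPM), Sst, Hsph1, Hamp (0.503 and 4.46 CPM), Ifi44, Oas2 (1.94 and 9.63 CPM), Hspa1b (72.2 and 232 CPM), Ifi27l2a (9.16 and 30.9 CPM), Hspb1 and Hspa1a (104 and 283 CPM). The hormone Sst rested on 5 knockout cells, of which 1 held most UMIs, and its direction turned in 5 alternatives. Hamp was seen in 15 knockout and 3 control cells, and Lyz1 in 6 and 10. Lower were Reg3b, Lyz1 (4.49 and 0.442 CPM), S100g (48.8 and 11.3 CPM), the bile acid transporter Slc10a2 (6.83 and 1.33 CPM), Reg3g, Slc51a, Tff2 (3.02 and 0.578 CPM), Cyp2c55, Acaa1b (3.59 and 0.918 CPM) and Tgm3 (29.5 and 10.5 CPM). The larger part of the S100g UMIs lay in 4 of 1104 control and 43 of 1031 knockout cells, and free RNA brings 4.67 and 5.38 CPM of it. For Tff2 the larger part lay in 3 control cells, for Slc10a2 in 13 and for Slc51a in 14. With cells thinned to 1000 UMIs and clustered again, S100g, Slc10a2, Cyp2c55 and Acaa1b turned direction. In colonocyte-like cells Cxcl9, AA465934, the interferon-induced GTPase Iigp1 (1.74 and 22.6 CPM), Slfn2 (1.95 and 24.0 CPM) and Slfn5 (3.24 and 31.8 CPM) were highest, and Ppy, Camk2b (5.37 and 1.89 CPM), Gdf15 (13.3 and 6.16 CPM), Bmf (2.09 and 0.887 CPM) and Hoxb3 (6.74 and 3.21 CPM) lowest. Of these, Ppy turned direction with the free RNA profile of 10 to 100 UMIs subtracted and Hoxb3 with cells thinned to 1000 UMIs. Cxcl9 was seen in 47 of 5450 knockout and 8 of 4934 control colonocyte-like cells, and 4 knockout cells held most of its UMIs there. Over all epithelial cells the highest were Capn11, with 0 control UMIs and at least 31.9-fold higher against a floor of 3 counts, AA465934, Ghrl, Slfn5 and Cxcl9. The lowest were Ppy (33.3 and 2.01 CPM), Lyz1, Tff2, Fabp1 and Neurog3, and 2 control cells held most Ppy UMIs. Ghrl was seen in 10 knockout and 8 control cells and Neurog3 in 4 and 11.

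**Figure D2:**
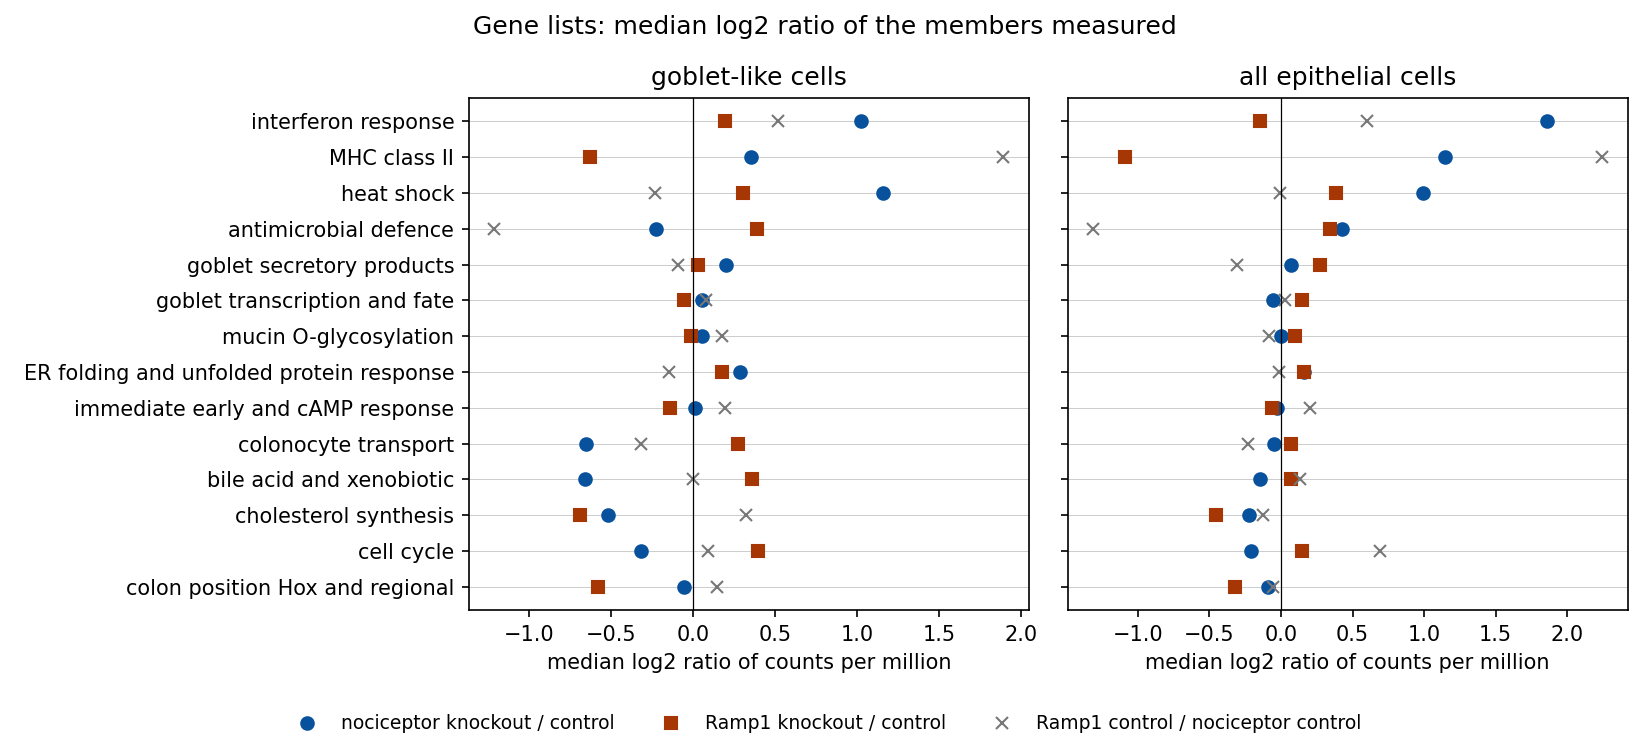
Median log2 ratio of 14 gene lists in goblet-like cells and in all epithelial cells for both knockout comparisons and for the control libraries against each other, 1 library per group. Interferon response genes reach 1.86 in all epithelial cells of the nociceptor comparison, and MHC class II genes stand at 1.15 and -1.09 in the nociceptor and Ramp1 comparisons.

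The Ramp1 comparison asks how epithelial cells differ when they lack Ramp1. Goblet-like cells of the knockout held 94.7 CPM of Ramp1 against 998 CPM in the control, 10.5-fold lower (10.1 to 11.0), and more of the secreted products Retnlb, Ang4, Itln1 and Clca1. Genes of cholesterol synthesis were lower in goblet-like cells (median log2 ratio -0.69), as were MHC class II genes in all epithelial cells (-1.09). The metallothionein Mt1 was higher in goblet-like cells, colonocyte-like cells and all epithelial cells. Calcrl stood at 2.52 CPM in control and 2.45 CPM in knockout goblet-like cells (-0.04, -0.59 to 0.50). Its ratio of knockout to control CPM was 1.39 (1.08 to 1.78) over all epithelial cells and 1.67 (1.20 to 2.35) outside goblet-like cells. Within each named class the interval of this ratio held 1.

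At 5000 UMIs per cell, 34.9% (31.9 to 37.9) of knockout goblet-like cells still carried a Ramp1 UMI, against 90.7% in the control and 0.222% of knockout colonocyte-like cells. Without thinning these shares were 72.5%, 95.2% and 0.382%, at medians of 22227, 23830.5 and 21276 UMIs. Thinned to 5000 UMIs, 8 of 1015 knockout goblet-like cells carried at least 4 Ramp1 UMIs (0.788%), against 607 of 969 control goblet-like cells (62.6%). Cycling cells held 54.6 CPM in the control and 8.02 CPM in the knockout, enteroendocrine-like cells 125 and 14.9 CPM, and tuft-like cells 55.7 and 3.08 CPM (3 UMIs, interval 0.636 to 9.01). Within the cycling class, cluster 19 held 499 and 45.3 CPM.

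Goblet-like cells were 12.9% (12.2 to 13.7) of the Ramp1 control and 14.1% (13.3 to 14.9) of the knockout, a ratio of 1.09 (1.005 to 1.18). Tuft-like cells were 0.674% and 1.05% (1.56, 1.10 to 2.21), cycling cells 9.68% and 11.0% (1.14, 1.03 to 1.25) and stem-like cells 5.04% and 5.73% (1.14, 0.995 to 1.30). Enteroendocrine-like cells were 0.687% and 0.906% (1.32, 0.924 to 1.89) and colonocyte-like cells 44.8% and 44.7% (0.998, 0.963 to 1.03). Cells of unnamed clusters were 26.2% and 22.6% (0.861, 0.815 to 0.911). Shares sum to the whole, so higher shares of named classes go with this lower one.

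**Figure D3:**
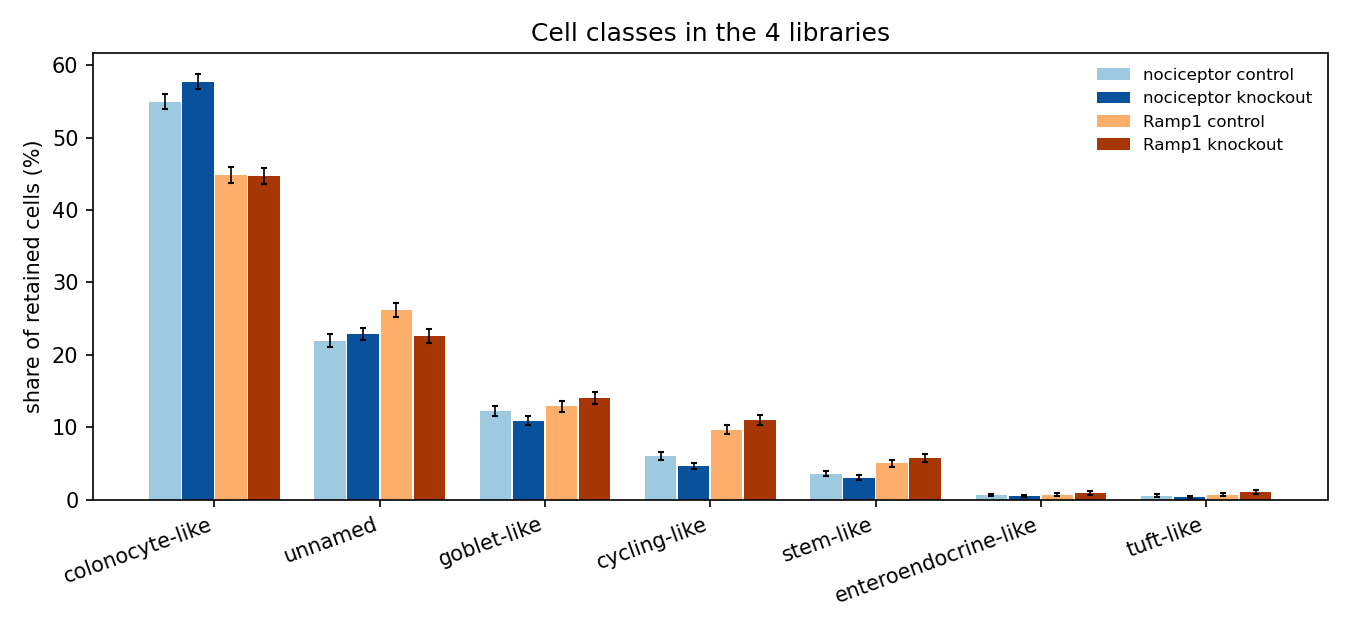
Share of retained cells in each named class and in the unnamed clusters per library, in percent, with 95% Clopper-Pearson intervals that cover counting error only. Goblet-like cells take 12.3%, 10.9%, 12.9% and 14.1% in the nociceptor control, nociceptor knockout, Ramp1 control and Ramp1 knockout.

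Of 15 goblet secretory products, 4 were higher and 0 lower in knockout goblet-like cells, with a median of 0.03 (percentile 86.4). Within clusters the medians were 0.15 with 5 higher in cluster 5, 0.26 with 7 higher in cluster 9 and -0.17 with 3 higher and 3 lower in cluster 18, and the shares of these clusters differ between the libraries. Outside goblet-like cells the list stood at 0.48 in colonocyte-like cells (7 of 15 higher), 0.76 in cycling cells (10 of 15 higher) and 0.34 in stem-like cells (3 of 14 higher, 1 lower), with free RNA left in. The Muc2-rich cluster 19 was 9.91% of the cycling class in the control and 14.5% in the knockout, so the cycling value may reflect this mix in part. Retnlb stood at 440.3 and 1459 CPM (1.73, 1.70 to 1.76), Ang4 at 465 and 1459.5 CPM (1.65, 1.62 to 1.68), Itln1 at 19.9 and 52.2 CPM (1.39, 1.23 to 1.54) and Clca1 at 3819 and 6087 CPM (0.67, 0.66 to 0.68). Fcgbp (0.49), Agr2 (0.20), Muc2 (0.15), Zg16 (0.03), Klk1 (-0.00), Muc13 (-0.02), Pigr (-0.03), Spink4 (-0.05), Tff3 (-0.08), Reg4 (-0.32) and Sval1 (-0.53) made up the rest. Ang4 and Retnlb in the knockout still lay below both nociceptor libraries. The antimicrobial list had 5 of 13 higher and 1 lower (0.39), with Reg3b at 32.9 and 137 CPM (2.05) beside Retnlb. Within cluster 5 Reg3b stood at 12.8 CPM in the control and 14.3 CPM in the knockout, with overlapping intervals. It stood at 32.4 and 73.6 CPM in cluster 9 and at 184 and 910 CPM in the smaller cluster 18. The higher Reg3b value thus lay in clusters 9 and 18 and not in cluster 5.

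**Figure D4:**
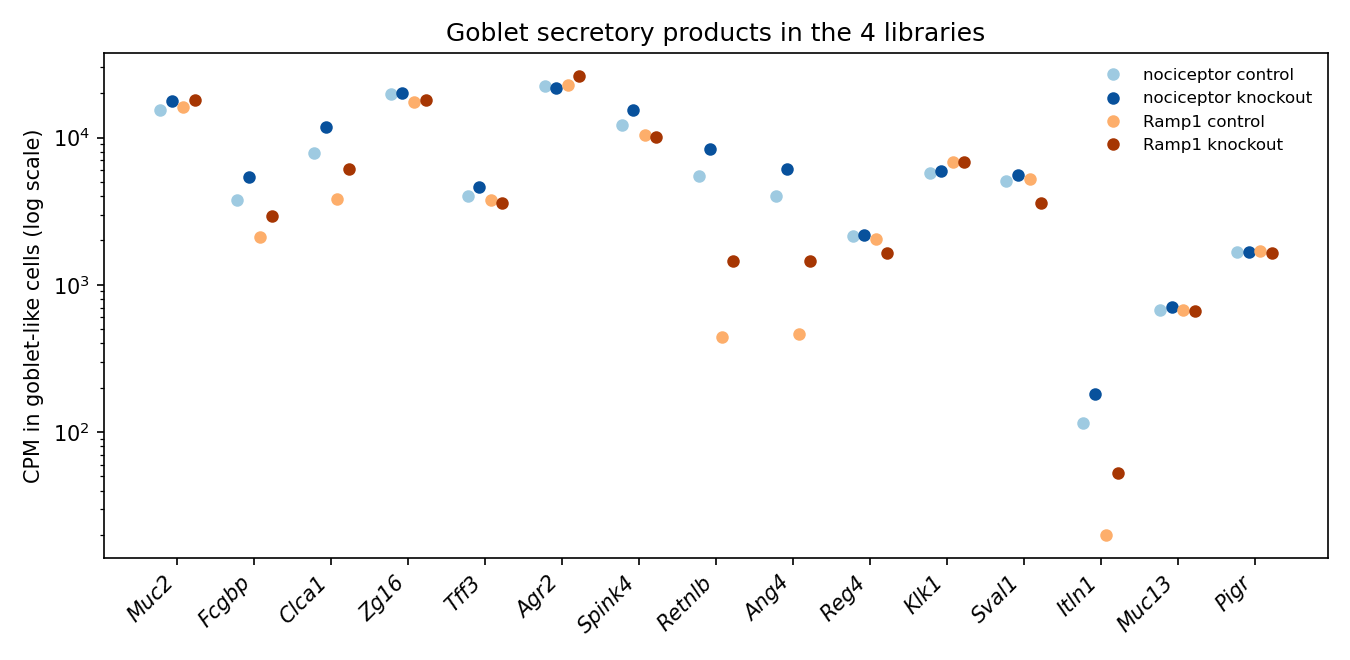
CPM of goblet secretory products in goblet-like cells of the 4 libraries on a log axis, 1 dot per library. Ang4 stands at 4002 and 6144 CPM in the nociceptor control and knockout, while Muc2 lies between 15450.1 and 17943 CPM in all 4 libraries.

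Cholesterol synthesis genes had 9 of 16 lower and 0 higher in knockout goblet-like cells (percentile 0). Insig1 (chromosome 5, 28071363 to 28078662), a sensor of sterol levels, stood at 95.4 and 39.6 CPM (-1.27, -1.38 to -1.16) and Hmgcs1 at 278 and 128 CPM (-1.12, -1.18 to -1.05). The list stood at -0.46 in all epithelial cells, -0.27 in colonocyte-like, -0.45 in cycling and -0.48 in stem-like cells, and between the controls at 0.33 in goblet-like cells. MHC class II genes had 6 of 7 lower in all epithelial cells, with H2-Aa at 37.3 and 10.1 CPM (-1.89) and H2-Eb1 at 29.2 and 10.4 CPM (-1.50), 6 of 7 lower in colonocyte-like cells (-1.20) and 3 of 6 lower in goblet-like cells (-0.62). The interferon list stood at -0.15 in all epithelial cells with 1 of 15 lower and at 0.20 in goblet-like cells, with Ifit2 at -1.19 and Isg15 at 0.94. Within cluster 5 the interferon median was 0.66 with 8 of 13 higher and 0 lower, and within cluster 9 it was 0.05 with 1 of 15 higher and 3 lower.

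Hox and regional genes had 7 of 16 lower and 1 higher in goblet-like cells (-0.58), with Hoxd11 at 2.48 and 0.635 CPM (-1.97, -2.89 to -1.13) and Hoxd10 at 0.841 and 0.296 CPM (-1.51, -2.99 to -0.21). This list stood at -0.42 in stem-like, -0.12 in cycling, -0.02 in colonocyte-like and -0.32 in all epithelial cells. Between the controls it stood at 0.15 in goblet-like and -0.38 in colonocyte-like cells. Cell cycle genes had 6 of 19 higher (0.40), with the replication factor Mcm5 at 4.16 and 8.16 CPM and the mitotic kinase Aurkb at a log2 ratio of 0.84. Colonocyte transport genes had 5 of 16 higher and 1 lower in goblet-like cells (0.27), with Car1 at 1107 and 2763 CPM and the sodium-hydrogen exchanger Slc9a3 at 6.02 and 14.2 CPM. The larger part of the Car1 UMIs lay in 25 of 996 control and 26 of 1070 knockout goblet-like cells. The transport median lay between 0.04 and 0.48 over the alternatives, was lowest without doublet removal, and stood at 0.20, 0.05 and 0.07 within clusters 5, 9 and 18. Bile acid and xenobiotic genes had 5 of 14 higher and 1 lower (0.36), with Gsta1 at 3.07 and 9.48 CPM and Slc51a at 9.04 and 19.0 CPM. Heat shock genes had 1 of 11 higher (0.30), with Hsph1 at 16.9 and 28.4 CPM and Hspa8 at 751 and 1085 CPM, and in colonocyte-like cells 3 of 10 (0.45), with Hspa1a at 67.6 and 182 CPM and Hspa1b at 31.2 and 82.9 CPM.

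The other lists lay between -0.36 and 0.18 in goblet-like cells. These were ER folding (0.18, Creld2 0.49 and Hspa5 0.43), granule exocytosis (0.03, Rab37 0.32 and Exph5 -0.22), mucin O-glycosylation (-0.01, St3gal1 0.55 and St3gal4 0.53), stem and Wnt (-0.05, Lgr5 1.10 and Myc -0.68) and goblet fate (-0.06). The goblet fate list held Spdef, a goblet transcription factor that leads cluster 9, at 300.1 and 462 CPM (0.62) and Dll1 at -0.55. Further lists were junction genes (-0.09, Tjp1 -0.34 and Cldn2 0.30), cytokines and chemokines (-0.10, Tslp -1.35 and Csf1 -0.69) and immediate early genes (-0.14, Per1 -0.35 and Zfp36 -0.32). The CGRP receptor list had a median of -0.06, with Crcp at -0.06 and Adm at -0.06 beside Ramp1 and Calcrl. Tac1 of the nociceptor list stood at 4.04 and 3.13 CPM, and Xist, the measured sex gene, at -0.22.

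Ranked as above, C1qa, Mal (4.80 and 16.2 CPM), Car1, Gsta1, S100g (43.1 and 107 CPM), Sptssb (21.2 and 51.3 CPM), Ppfia3 (10.7 and 25.6 CPM), Mt1 (397 and 832 CPM), Tmigd1 (20.3 and 45.9 CPM) and Slc10a2 (9.13 and 21.7 CPM) were highest in knockout goblet-like cells. The complement gene C1qa, at 1.18 and 6.51 CPM, was seen in 37 of 1070 knockout cells. Among the lowest were Ramp1, Xlr3b (4.29 and 0.296 CPM), Lyz1, Cldn14 (25.5 and 9.05 CPM), Insig1, Hmgcs1, Chodl (7.07 and 2.83 CPM), the serotonin receptor Htr4 (log2 ratio -1.47) and Pdlim4 (17.7 and 8.21 CPM). Chodl turned direction with cells thinned to 1000 UMIs. In colonocyte-like cells Gal3st2c (0.611 and 8.11 CPM), St3gal5 (0.538 and 3.53 CPM), Mt1 (618 and 2145 CPM) and Hspa1a were among the highest, and Ramp1, Xlr3b, Lce3b, Cxcl10 (4.66 and 1.49 CPM) and Phlda1 (83.1 and 32.2 CPM) lowest. Lce3b and Cxcl10 turned direction with a mitochondrial limit of 10%, and Ramp1 in colonocyte-like cells with the free RNA profile of 10 to 100 UMIs subtracted. Over all epithelial cells Ooep, C1qa, St3gal5 and Mt1 (678 and 1719 CPM) were among the highest, and Ramp1, Ppy, Xlr3b, Lyz1 and Lce3b were lowest. Ooep was seen in 16 knockout cells, of which 1 held most UMIs, and in 11 control cells, Lyz1 in 5 and 11 and Lce3b in 5 and 8.

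Both knockouts were set side by side to ask whether loss of nociceptors and loss of epithelial Ramp1 leave the same mark on goblet-like cells. Across 11647 genes the log2 ratios of the comparisons had a Pearson correlation of -0.18, a Spearman correlation of -0.13 and a covariance of -0.016. Simulated data with no effect gave a Pearson value of -0.0038. The simulation held counting noise and no spread between libraries, so it cannot show whether -0.18 departs from no effect. Genes are not independent replicates and no p-value is given. Pairing the same libraries in the other ways gave Pearson values of -0.55 and 0.40. Those pairings set nociceptor against Ramp1 libraries, and their covariances add up to the one above by construction, so they are no independent benchmark. With cells thinned to 1000 UMIs the correlation was 0.023. Summed over the goblet-like class, Ang4, Retnlb and Itln1 were higher and Lss and Hmgcs1 lower by a fold of at least 1.5 in both comparisons. Within cluster 5 of the nociceptor pair 0 of 15 goblet products reached that fold, with Ang4 at 6493 and 9025 CPM, control first. Retnlb of that pair stood at 2724 and 5027 CPM in cluster 9 and at 1506 and 1309 CPM in cluster 18, so its direction differed by cluster. Over the alternatives the Ang4 ratio of the nociceptor pair lay between 1.25 and 1.70, so not all reach that fold. Car1, Aqp8, Slc51a, Reg3b and Slc10a2 were lower in the nociceptor knockout and higher in the Ramp1 knockout. Some of these rest on few goblet-like cells. The larger part of the Slc10a2 UMIs lay in 13 nociceptor control cells, and in 21 knockout and 16 control cells of the Ramp1 pair. Slc10a2 also turned direction in the nociceptor pair with cells thinned to 1000 UMIs. Doublets with colonocytes were examined in the nociceptor pair alone.

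The control libraries differed from each other about as much as each knockout from its control in goblet-like cells, and more in all epithelial cells. In goblet-like cells 95% of genes lay within a log2 difference of 0.54 between controls, 0.58 in the nociceptor comparison and 0.50 in the Ramp1 comparison, and in all epithelial cells within 0.75, 0.51 and 0.47. Xist, expressed from the inactive X of females, stood at 582 and 566 CPM in the Ramp1 libraries and at 0.114 and 0.453 CPM in the nociceptor libraries, where the Y-linked Ddx3y stood at 24.8 and 27.6 CPM. Sex is thus matched within each comparison and differs between them.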

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

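The tests on Ramp1 left in the Ramp1 knockout, the comparison of interferon genes between the controls, and the tests of unequal free RNA and of the cluster mix as the whole source of absorptive transcripts were chosen only after the result was seen.

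Several values went opposite ways in the knockout comparisons, each from 1 library against 1, and no difference between the comparisons was tested. The share of cycling cells had a knockout over control ratio of 0.767 in the nociceptor pair and 1.14 in the Ramp1 pair, and the share of goblet-like cells 0.888 and 1.09. The goblet-like ratio of the nociceptor pair was 1.06 with cells thinned to 1000 UMIs and 1.07 with the low-UMI cluster counted as goblet-like, so both pairs go the same way under these settings. MHC class II genes such as H2-Aa and Cd74 had median log2 ratios of 1.28 and -1.20 in colonocyte-like cells and 1.15 and -1.09 in all epithelial cells. In colonocyte-like cells the Ramp1 control stands 2.24 above the nociceptor control in this list, so both knockouts lie between the controls there. The cluster of low-UMI barcodes, which belongs to no named class and counts only among all epithelial cells, held 4.41% of the nociceptor knockout against 1.97% of its control.

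Interferon response genes such as Ifi44, Ifit2 and Isg15 were higher in the nociceptor knockout library by a median of 1.86 over all epithelial cells. Without the 240 control and 253 knockout barcodes that hold an immune marker UMI the median was 1.86, and after subtraction of free RNA it was 1.86, which argues against immune cells or free RNA as the whole source. Spread between libraries that has nothing to do with the knockout cannot be told apart from an effect of nociceptor loss: the controls differ by 0.60 in this list, and 1 such pair does not show how far libraries can differ. A higher interferon tone without nociceptors may be a hypothesis for replicate libraries, and infection or housing of single mice was not tested.

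Absorptive transcripts such as Aqp8 and Car1 were lower in goblet-like cells of the nociceptor knockout by a median of -0.65. The median was -0.48 without the goblet-like cells richest in colonocyte markers (110 control and 103 knockout cells removed), -0.74 after subtraction of free RNA and -0.51 within cluster 5. Within clusters 9 and 18 it was -0.38 and -1.33, so the direction is the same in each goblet-like cluster. Free RNA, taken at the mean content of empty droplets, was nearly level between the libraries (Aqp8 at 6.50 and 6.20 CPM, control first) and alone would give a median of 0.00023, which argues against it as the source. The cluster shares of the knockout alone would give -0.27, which argues against the mix of clusters as the whole source. As part of the source, this mix cannot be told apart from a difference within goblet cells, and neither can doublets with colonocytes. What keeps doublets and the mix open is that the values of -0.48 and -0.51 lie between the bounds set beforehand. The markers used for removal include Aqp8, Car1, Car4 and Slc26a3 of the transport list. Removal can thus shrink the median whether or not the cells are doublets, so -0.48 cannot decide on doublets. In goblet-like cells the Ramp1 control stood at -0.32 against the nociceptor control in this list, with 7 of 16 genes lower and 1 higher. Spread between libraries unrelated to the knockout therefore stays open too.

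Ramp1 left in goblet-like cells of the Ramp1 knockout stood at 94.7 CPM. If it came from cells that escaped deletion with full expression, 8.60% of goblet-like cells would hold a Ramp1 UMI at 5000 UMIs, whereas 34.9% did. Free RNA brings 0.207 CPM. Both values argue against these as the source of what is left. Transcripts from the shortened allele whose 3′ tags lie outside the deleted part may account for it, as a hypothesis that was not tested, since the labels do not give that part.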

How the results depend on the processing

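The alternatives were fixed before the data were examined, except the 200 to 700 UMI free RNA profile, the low-UMI cluster counted as goblet-like and clustering without the genes of 6 lists, which were chosen after seeing the data. Running the alternatives on Ang4 and on the interferon, heat shock, MHC class II, transport and cholesterol lists was also decided after seeing the data. No paired analysis was possible because each group has 1 library, and no result has a test. Where a value moved or turned, the cause was not tested.

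The goblet-like share ratio of the Ramp1 pair lay between 1.07 and 1.12 in all 14 alternatives. Median log2 ratios kept their direction for interferon genes (1.62 to 1.87), heat shock genes (0.94 to 1.02), MHC class II genes (1.12 to 1.31 and -1.15 to -1.07 in the nociceptor and Ramp1 pairs), colonocyte transport genes (-1.41 to -0.21 and 0.04 to 0.48) and cholesterol genes (-0.55 to -0.44 and -0.75 to -0.63). Ang4 ratios lay between 1.25 and 1.70 and between 2.62 and 3.19. Between 73 and 80 of 80 ratios of named genes, where a gene can count in several classes, kept their direction, and 120 of 126 list medians kept their sign with a minimum of 100 UMIs.

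In the following, the Ramp1 ratio is goblet-like over other cells, in the nociceptor and then the Ramp1 control, and products are the median log2 ratios of goblet products in the nociceptor and then the Ramp1 pair. With a minimum of 500 UMIs the Ramp1 ratios were 45.6 and 85.2 and products 0.15 and 0.0072. With 2000 UMIs products were 0.19 and 0.011, and Sst in goblet-like cells of the nociceptor pair was -0.72. With the limit set from the 99th percentile the Ramp1 ratios were 55.4 and 85.9, products of the Ramp1 pair 0.041 and the correlation -0.27.

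With a mitochondrial limit of 10% the Ramp1 ratios were 43.8 and 66.2, products 0.17 and 0.013 and the correlation -0.25. In the Ramp1 pair Lce3b was 1.36 in all and 1.49 in colonocyte-like cells, and Cxcl10 0.32. With a limit of 40% the goblet-like share ratio of the nociceptor pair was 0.972, the Ramp1 ratios 72.3 and 118, products 0.14 and 0.013, the correlation -0.11 and Sst -1.92. Without doublet removal the Ramp1 ratios were 155 and 234, products 0.23 and 0.0076 and the correlation -0.12. At resolution 0.5 products of the Ramp1 pair were 0.027. Sst was -1.92 at resolution 2 and -1.91 with genes scaled within each library.

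With the 10 to 100 UMI profile subtracted, Ramp1 over all cells stood at 0.122 of its control, the Ramp1 ratios were 1144 and 6796 and the correlation -0.51. In colonocyte-like cells Ppy was 4.91 (nociceptor pair) and Ramp1 3.90 (Ramp1 pair). With the 200 to 700 UMI profile the Ramp1 ratios were 67.4 and 107.

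With cells thinned to 1000 UMIs, the goblet-like share ratio of the nociceptor pair was 1.06, Ramp1 over all cells 0.119 of its control, the Ramp1 ratios 103 and 120.4, products 0.0028 and 0.070 and the correlation 0.023. Hoxb3 was 0.01 in colonocyte-like cells of the nociceptor pair. In goblet-like cells of that pair Sst was -3.70, S100g 0.48, Slc10a2 0.35, Cyp2c55 0.30 and Acaa1b 0.10, and in the Ramp1 pair Chodl was 0.12. Cells were clustered again after thinning, so a lower depth also changes which cells are called goblet-like.

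With ratios centred on their median, products were 0.28 and 0.053. With the low-UMI cluster counted as goblet-like, the share ratio of the nociceptor pair was 1.07, its products 0.19 and the correlation -0.15. Clustering without the genes of 6 lists gave products of 0.18 in the nociceptor pair.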

Other observations

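No test in this part was chosen after a result was seen, because none was run: these are values.

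Cholesterol synthesis genes had negative medians in goblet-like cells of both knockouts, with Lss at 18.2 and 10.4 CPM in the nociceptor pair and 27.7 and 15.8 CPM in the Ramp1 pair, control first, and Idi1 at log2 ratios of -0.49 and -0.85. Idi1 and Lss encode enzymes of sterol synthesis. By cluster the list median of the nociceptor pair was -0.67 in cluster 5 and -0.10 in cluster 9, where 0 of 16 genes were lower, and that of the Ramp1 pair -0.44 and -0.90. Lyz1, a lysozyme of Paneth-type cells, stood at 4.49 and 0.442 CPM and at 5.93 and 0.888 CPM in goblet-like cells, and at most 2 cells held most of its UMIs in any of the 4 libraries.

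Within goblet-like cells Ramp1 differed by cluster, though Ramp1 is itself among the 10 leading genes of cluster 5 and was not left out of the clustering. Cluster 5 held 1100.1 CPM in the nociceptor control and 1379 CPM in the Ramp1 control, cluster 9 held 670.5 and 668 CPM and cluster 18 held 382 and 268 CPM. In the Ramp1 knockout these clusters held 137, 74.9 and 30.5 CPM. Within cluster 5 of the Ramp1 pair, Ang4 stood at 807 and 3313 CPM and Retnlb at 379 and 2539 CPM, and in cluster 9 at 41.3 and 154 CPM and at 554 and 868 CPM, so the higher values of these antimicrobial products in the knockout are found within clusters and not only in their mix.

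The control libraries differed widely in antimicrobial products over all epithelial cells: Ang4 stood at 639 CPM in the nociceptor control and 68.2 CPM in the Ramp1 control, Retnlb at 867 and 66.2 CPM and Reg3g at 265 and 65.7 CPM. The MHC class II chain Cd74 stood at 43.6 and 249.8 CPM.

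Hormone genes rested on few cells. In the nociceptor control 2 of 165 cells with a Ppy UMI held most of them, and in the Ramp1 control 2 of 125. Ghrl was seen in 10 cells of the nociceptor knockout and 8 of its control, and 2 knockout cells held most of its UMIs.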
